A study of Pseudomonas aeruginosa with 6 samples.

How the data were processed

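RNA from 6 cultures of P. aeruginosa PAO1, 3 grown at 28 °C and 3 at 37 °C, was measured on one-colour Agilent arrays. The strain name is spelled PAO1 in the series title, which is followed here, and PA01 in the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and amplified into Cy3-labelled cRNA. Per the file headers, spot intensity was read with Agilent Feature Extraction 10.5.1.1, whereas the submitters' processing notes name version 9.1. The deposited scanner files give, per spot, the raw mean and local background intensity, a processed intensity after background subtraction and detrending, and flags, per the file headers. The intensity values in the authors' whole-series table equalled the processed intensity of the same array at every spot (largest difference 0), so they are linear and not centred or normalised between arrays. The medians of its 6 columns were 925.0, 966.3 and 707.0 at 28 °C and 570.2, 543.3 and 633.5 at 37 °C. The design text describes the experiments as independent.

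Each array carried 6773 probe names of 60 bases, 6613 with 2 spots each and 160 with 10. Names that shared a sequence were merged, which left 6693 distinct probes, and 72 sequences had more than 1 name. Control spots and spots flagged as non-uniform or population outliers (36 to 65 per array) were left out, and saturated spots would have been kept. The log2 processed intensity minus each array's 75th percentile of that value was averaged over the spots of a probe. A probe counted as well above background on an array when at least 0.5 of its spots did, and was tested if it did so on all 3 arrays of at least 1 temperature, which 6140 probes met. The spike-in control probes lay at the floor and the spike-in fit had a slope of 0 on every array, so the scaling could not be checked against spike-ins.

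The difference, 37 °C minus 28 °C, was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with 4 residual degrees of freedom and Benjamini-Hochberg adjustment over tested probes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data with the 6140 probes' own means and spreads and 200 changed probes, the fit recovered 95% of 2-fold and 98% of 4-fold changes, all in the right direction. It made 16 false calls, 7.66% of its calls, against the nominal 5%. The simulated values had independent normal noise, no scaling or slide differences between arrays, and changes of 2- or 4-fold only. The simulation therefore does not bear on the scaling, on the slides or on smaller changes.

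The probe identifiers matched 0 locus tags or symbols of the 5697 genes in the RefSeq table of assembly ASM676v1, and no description or position was given for any probe. The 42 gene lists and the rule for named genes fixed before the data were examined therefore were not applied, except for the part covering features without a symbol, namely the 2 largest rises and the 2 largest falls among called probes whose values at the temperatures do not overlap. For the same reason, several probes of a gene could not be combined, and a probe's value is not a gene's value.

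In place of the gene lists, 20 classes were defined from probe sequence after the layout of the files was known and before any temperature difference was computed. They comprised 18 peptide motifs, a mean Kyte-Doolittle hydropathy of at least 1.6, and a GC content below 45%. The reading frame was the open sense-strand frame with the highest GC content at the third codon position. This rule chose the frame that starts with the start codon in 91.4% of the 268 probes that begin with one, and the frame that ends with the stop codon in 70.3% of the 286 that end with one. A similar number, 281, began with the reverse complement of a stop codon, so many of the 286 may not hold a true stop. The reverse complement of a start codon came last in 47 probes, so some of the 268 may not hold a true start. These shares therefore do not measure how often the frame is right, and some peptides may be misread. A class was tested with camera (preset correlation 0.01) if it had at least 4 tested probes and at most 1 match to reversed peptides. This left 7 classes, and 1 more, with 3 tested probes, is given as values only. The DEAD box and EAL motifs each matched 4 reversed peptides, and the remaining motifs had fewer than 4 probes.

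The alternatives tried were normexp background correction with an offset of 50, followed by quantile normalisation or the 75th percentile shift, quantile normalisation or a median shift of the processed intensity, the authors' table, no filter or a filter on all arrays, flagged spots kept, a trended and robust variance, the slide as a block, slide 2 alone, a replicate block and leaving out each array in turn. Keeping probe names with one sequence apart was added after the data were seen.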

Results

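Transcript levels of Pseudomonas aeruginosa PAO1, a widely used laboratory strain of this opportunistic pathogen, were measured in cells grown in LB medium at 28 °C or at 37 °C to late exponential phase, at an OD600 of 5.0 to 6.0. Per the series' design text, each temperature was covered by 3 independent experiments, and each experiment was hybridised to 1 one-colour (Cy3) Agilent array, giving 6 arrays. Each array held 14826 spots that were not controls. Between 91.4% and 93.2% of the non-control spots were well above background on each array, and no such spot was saturated. The 75th percentile of the processed spot intensity was 2170.5, 2205.5 and 1754 on the 28 °C arrays of replicates 1, 2 and 3, and 1254, 1243 and 1527 on the corresponding 37 °C arrays. The number of arrays limits the precision of every value below. The array files gave probe identifiers and probe sequences and did not pair them with genes, so the measured unit was the probe, and no probe was assigned a gene or a genomic position.

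The comparison asked which transcripts differed in level between growth at 37 °C and at 28 °C. Of 6140 probes tested, 2812 (45.8%) differed at an adjusted p below 0.05 in limma, 1677 of them higher and 1135 lower at 37 °C. Most of these differences were small, with a median of 1.43-fold among the probes that were higher and 1.47-fold among those that were lower at 37 °C. At a threshold of 2-fold, 411 probes remained, and here the falls outnumbered the rises, with 178 higher and 233 lower at 37 °C. At 4-fold 16 probes were higher and 45 were lower, and at 8-fold 4 were higher and 5 were lower. The 3 values at 37 °C did not overlap the 3 values at 28 °C for 2756 of the 2812 probes. Among all tested probes the share without overlap was 56.2%, against 10% for a chance ordering of 3 and 3 values.

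**Figure D1:**
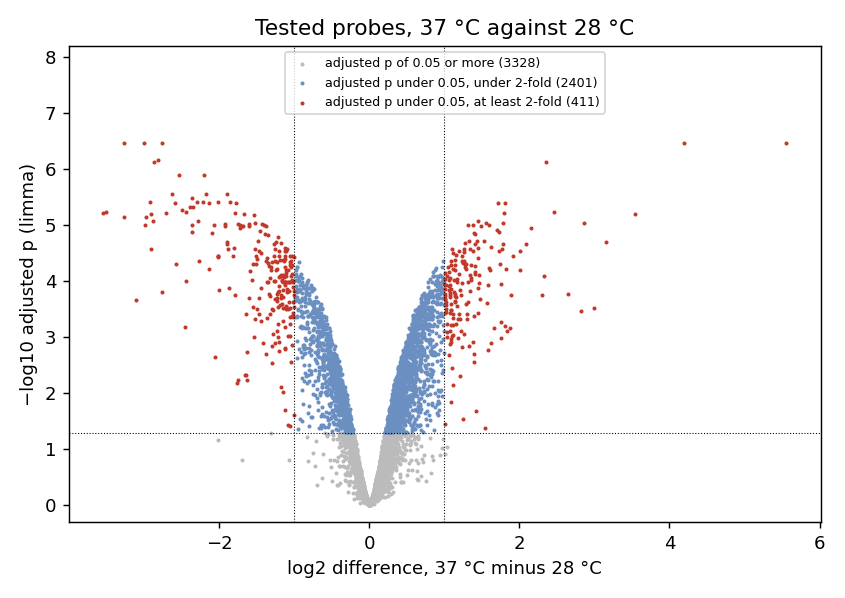
The log2 difference between 37 °C and 28 °C (x axis) is plotted against the negative log10 of limma's adjusted p (y axis) for the 6140 tested probes, with dotted lines at 2-fold and at an adjusted p of 0.05. Grey points are the 3328 probes that did not pass the test, and red points the 411 that passed it with a change of at least 2-fold.

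The arrays separated by temperature. Pearson's correlation across probes, which are not independent replicates, was 0.990 to 0.995 between arrays of one temperature and 0.951 to 0.959 between arrays of different temperatures. The first principal component carried 79.1% of the variance and held the 3 arrays of each temperature on opposite sides, while the second carried 7.19%. The arrays came from 2 slides, each scanned in a batch of its own. Slide 1 held 28 °C replicates 1 and 2, and slide 2 held 28 °C replicate 3 and the 3 arrays at 37 °C. With the slide as a block, 2167 probes were called, 1367 higher and 800 lower at 37 °C, and 477 changed at least 2-fold. Within slide 2 alone, where a single array stood for 28 °C and was assumed to vary like the 37 °C arrays, 2050 probes were called, 1265 higher and 785 lower, and 483 changed at least 2-fold. Slide 1 held arrays of 1 temperature only and gave no value. The fit with the slide as a block therefore also took each log2 difference from slide 2, against the same single 28 °C array. Here and below, the block and slide 2 alone gave the same log2 differences and are not separate checks.

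The largest rise belonged to probe CUST_522_PI422601732, of sequence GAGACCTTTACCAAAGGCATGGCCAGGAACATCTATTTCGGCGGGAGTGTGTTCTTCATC. Its normalised log2 signal was -1.999 ± 0.102 (SD, n = 3) at 28 °C and 3.56 ± 0.318 (SD, n = 3) at 37 °C. The log2 difference of 5.56 (SE 0.153) corresponded to 47.1-fold and had a limma adjusted p of 3.36e-07. Probe CUST_525_PI422601732, of sequence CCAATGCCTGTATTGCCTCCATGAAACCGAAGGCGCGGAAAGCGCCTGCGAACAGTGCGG, was next. It rose from -1.14 ± 0.164 to 3.05 ± 0.0888 (SD, n = 3 each), a log2 difference of 4.19 (SE 0.104), which is 18.2-fold, with a limma adjusted p of 3.36e-07. Within slide 2 the log2 differences of these probes were 5.56 and 4.26, and with the slide as a block their limma adjusted p was 1.58e-05 and 1.44e-05.

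The largest fall belonged to probe CUST_4743_PI422601732, of sequence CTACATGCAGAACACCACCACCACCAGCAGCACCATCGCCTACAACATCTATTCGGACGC. Its normalised log2 signal was 3.14 ± 0.384 (SD, n = 3) at 28 °C and -0.41 ± 0.139 (SD, n = 3) at 37 °C. The log2 difference was -3.54 (SE 0.180), so the signal was 11.7-fold higher at 28 °C, with a limma adjusted p of 5.99e-06. Probe CUST_2023_PI422601732, of sequence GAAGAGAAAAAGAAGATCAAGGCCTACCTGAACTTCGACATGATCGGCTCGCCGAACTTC, went from 2.41 ± 0.342 at 28 °C to -1.10 ± 0.205 at 37 °C (SD, n = 3 each). Its log2 difference was -3.51 (SE 0.176), 11.4-fold higher at 28 °C, with a limma adjusted p of 5.85e-06. Within slide 2 the log2 differences of these probes were -3.97 and -3.904, and with the slide as a block their limma adjusted p was 1.44e-05 and 1.59e-05.

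**Figure D2:**
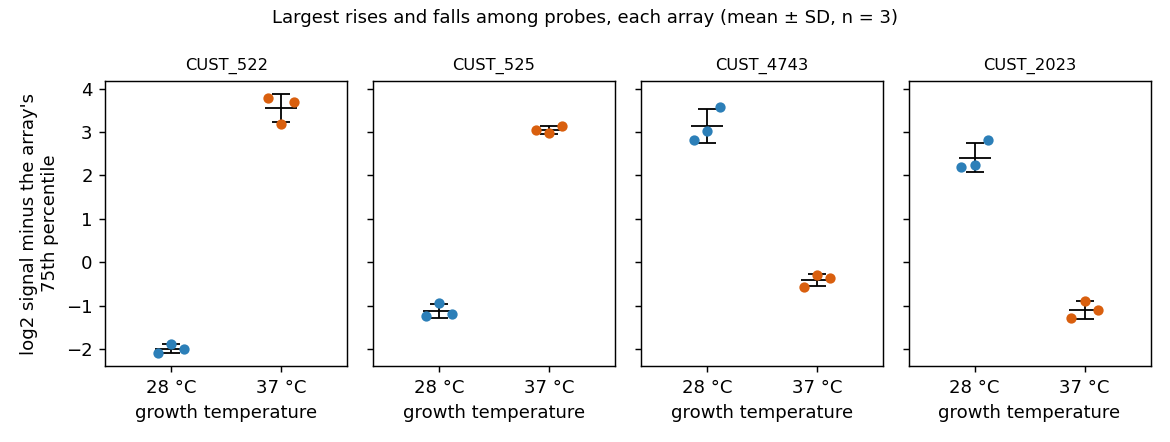
Each panel shows 1 of the 4 named probes, with the normalised log2 signal (y axis) of each array at 28 °C (blue) and 37 °C (orange), and black bars for the mean ± SD of 3 arrays. The 3 arrays of one temperature lie apart from the 3 of the other in every panel, which the rule that chose these probes required.

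Few probes were detected at only 1 temperature. Of 6693 distinct probes, 6041 were well above background on all 6 arrays and 313 on none. On all 3 arrays at 37 °C and none at 28 °C there were 3 probes, of which 2 passed the test. The first was at least 2.18-fold and the second 1.46-fold higher at 37 °C (limma adjusted p of 0.00148 and 0.017). With the slide as a block the second did not pass (limma adjusted p of 0.215), its log2 difference going from 0.54 (SE 0.147) to 0.31 (SE 0.181). The opposite pattern was seen for 3 probes, of which 1 passed, at least 1.95-fold higher at 28 °C (limma adjusted p of 0.000988). The bounds of at least 2.18-fold and at least 1.95-fold set the mean of the brighter group against the lowest signal among probes well above background on each array of the dimmer group, or the probe's own signal where that was higher. For the probe at 1.46-fold its own signal at 28 °C was the higher, so that value is the fitted difference and not a bound.

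Since no gene lists could be applied, probes were grouped by what their own sequence encodes, read in the open frame with the highest GC content at the third codon position. A match to a motif's pattern does not establish that the protein has the site, and some peptides may be read in the wrong frame. Of 6 probes matching the pattern of the loop beside the phosphorylated aspartate of response regulators, the regulators of 2-component signalling, 3 were higher at 37 °C, 2 were lower and 1 did not pass the test, and their log2 differences ran from -0.96 to 1.75. With the slide as a block, 1 was higher and 2 were lower. The log2 differences of the rises that were no longer called changed little, from 0.48 (SE 0.141) to 0.46 (SE 0.208) and from 0.42 (SE 0.095) to 0.38 (SE 0.137), while their SEs grew. Of 6 probes matching the short pattern of the redox site of thioredoxins, 3 were lower at 37 °C and none was higher, with a median log2 difference of -0.17, and 2 stayed lower with the slide as a block. The peptides of these 2 were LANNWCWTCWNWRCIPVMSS and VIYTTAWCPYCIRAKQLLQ. Whether either belongs to a thioredoxin, or is read in the right frame, was not tested. The third lower probe went from -0.29 (SE 0.089) to -0.16 (SE 0.112), and the class median with the block was -0.08. Of 4 tested probes matching the pattern of the methylation site at the start of mature type IV pilins and pseudopilins, 3 were higher and none was lower, with a median of 0.29, and with the slide as a block 1 was called higher, with the class median still 0.29. The log2 differences of the rises no longer called went from 0.29 (SE 0.089) to 0.32 (SE 0.127) and from 0.30 (SE 0.088) to 0.24 (SE 0.123). Of 4 probes matching the pattern of the attachment site of haem in c-type cytochromes, 2 were higher and 1 was lower, with a median of 0.22, and with the slide as a block 1 was higher and 1 lower, with a median of 0.32. The rise no longer called kept its size but had a larger SE, at 0.43 (SE 0.11) before and 0.45 (SE 0.161) with the block. Of 4 probes matching a pattern of the TetR-type DNA-binding helix, 3 were lower and none was higher, with a median of -0.45, and these counts were the same with the slide as a block. One of the 3 lower probes has the peptide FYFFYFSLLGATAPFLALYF, which holds no charged residue. Whether any of the 4 belongs to a TetR-type regulator was not tested. The haem, TetR and thioredoxin patterns each also matched 1 reversed peptide, so chance matches occur, but this does not tell how many of the other matches are true. The matched peptides were not compared with known proteins, so the counts for every motif describe pattern matches and not proteins with the site.

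Probes encoding a strongly hydrophobic segment, as membrane-spanning parts of proteins do, numbered 238 tested, of which 65 were higher and 38 lower at 37 °C, with a median log2 difference of 0.11 against 0.09 for all tested probes. With the slide as a block, 44 were higher and 28 lower, and the median was 0.17 against 0.15 for all tested probes. Probes with less than 45% GC, low for this GC-rich species, numbered 147 tested, of which 62 were higher and 25 lower, with a median of 0.27. With the slide as a block, 42 were higher and 24 lower, and the median was 0.21 against 0.15 for all tested probes. Of the classes tested, those from motifs held only 4 to 6 probes each, so a shift of such a class could be missed. None of these 7 classes was called as shifted as a whole relative to the other probes in limma's camera test. Their adjusted p ran from 0.1625 to 0.6694 with the preset correlation and from 0.6742 to 0.8692 with an estimated correlation, and 0 classes had an unadjusted p below 0.05 in camera with the preset correlation. For the response regulator class the test's direction was down relative to other probes, although its median of 0.14 and mean of 0.10 were above the median of 0.09 for all tested probes. With the slide as a block the adjusted p ran from 0.2346 to 0.9314, and within slide 2 from 0.2701 to 0.7299. In both of these fits 1 class, the TetR pattern, had an unadjusted p below 0.05 in camera, at 0.0475 and 0.0390.

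Cold shock proteins are small RNA-binding proteins named for their induction on a drop in temperature. Of 4 probes matching the pattern of the RNA-binding site of the cold shock domain, 3 were tested, too few for the set test under the rule in use. Of these, 1 was higher at 37 °C, by a log2 difference of 0.40 (SE 0.085, limma adjusted p of 0.00594). The log2 differences of the other two were -0.31 (SE 0.116, limma adjusted p of 0.0562) and 0.06 (SE 0.125, limma adjusted p of 0.74). The fourth probe was well above background on no array.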

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

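The order of probes by design number, the sequence classes and the fit with probe names kept apart were added after the files were seen. The other alternatives, and the counts, were chosen before the data were examined. The count of changed probes, 2812, ranged from 2050 to 3168 over the 19 alternatives, and the count changed at least 2-fold, 411, from 352 to 483, so none moved either by over 1.5 times. Among the alternatives, the authors' table had to return the counts of 2812 and 411, since its values equal the processed intensity, and is not a separate check. Without each array in turn the counts were 2196 to 2535 and 409 to 431. The share of calls higher at 37 °C, 59.6%, ran from 53.6% with the median shift to 65.3% with normexp and the 75th percentile shift. Falls of at least 2-fold outnumbered rises in every alternative, most narrowly without 28 °C replicate 3, with 221 falls and 209 rises. The 4 named probes kept their direction and stayed below an adjusted p of 0.05 in limma under every alternative, and no sequence class was called under the alternatives run for the classes, which did not include the authors' table, flagged spots kept, the trended and robust variance or probe names kept apart. Unadjusted camera p fell below 0.05 for up to 3 of the 7 classes in some of them, 3 with normexp and the 75th percentile shift (lowest 0.0411), and the lowest was 0.0202, for the low-GC probes without 37 °C replicate 1.

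The correlations of same-numbered deviations from the group means were 0.118, -0.018 and 0.031, and not every array correlated best with its own number. These values gave no clear sign that the replicate numbers pair the arrays. Pairing cannot be excluded, since 28 °C replicate 3 lay on another slide than replicates 1 and 2. With the replicate number as a replicate block, 2860 probes were called, 1740 higher and 1120 lower, and 414 changed at least 2-fold. Not run were the probe of highest mean signal per gene and the alternatives for the gene lists, since both need the genes of the probes. Signal over background limits the 553 probes that were not tested.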

Other observations

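The tests of position on the array, of shared sequence, of residual background and of detection at matched GC content were set down before their results were seen, and the tests of a GC trend, of a difference between the slides, of GC content as the whole cause and of other splits of the arrays afterwards. All of the patterns were noticed in the data first, and the division into early and late probes was chosen after detection along the design had been seen.

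Probes with consecutive numbers in the array design changed together. The log2 differences of 5856 pairs of consecutive tested numbers correlated at r = 0.383 across probes, which are not independent replicates (permutation p = 0.0001, two-sided, the smallest that 10000 shuffles can give; Spearman's rho 0.361). The correlation fell with distance, to 0.263 at a distance of 2, 0.149 at 5 and 0.0403 at 10. There were 12 runs of at least 4 consecutive numbers that all changed at least 2-fold in one direction, 10 lower at 37 °C with 50 probes and 2 higher with 8 probes. In 1000 shuffles the most runs was 1 (permutation p = 0.001, one-sided, the smallest they can give). The longest run held 8 probes, lower at 37 °C with a median log2 difference of -2.09, or -2.34 within slide 2. A run of 5 probes fell furthest, with a median of -2.87, or -3.03 within slide 2. Another run of 5 lower probes went from a median of -1.145 to -0.77 within slide 2, below the 2-fold limit. The runs higher at 37 °C, of 4 probes each, had medians of 1.35 and 1.52, or 1.56 and 1.78 within slide 2.

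Spots that lie close together on the array do not account for this. Among 501 pairs whose spots all lay farther apart than random spots typically do, r was 0.466 (95% interval 0.394 to 0.532). Shared sequence does not either, since r was 0.380 (0.358 to 0.402) among 5836 pairs sharing no word of 12 bases. A candidate explanation is that consecutive numbers follow gene order, so that neighbours include genes of one operon. This was not tested, because the files do not place the probes on the genome, and no biological explanation was tested.

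Probes late in the design were more often above background on no array than early probes. Of 702 probes numbered above 6000, 198 (28.2%) were above background on no array, against 65 (1.18%) of 5492 probes numbered up to 5500, while 282 of the late probes were above background on all 6 arrays. At 50 to 60% GC the shares were 18.9% (exact 95% interval 15.2% to 23.1%) and 0.71% (0.48% to 1.0%). This gap exceeded the 5 points allowed if lower GC content were the cause but did not reach the 20 points set for excluding it. Taking the early share in each 5% bin of GC, 28.9 late probes (20.2 to 37.6) would be expected above background on no array, against 198 observed among the 700 late probes in those bins, so GC content may contribute but is not the whole cause. Whether the late probes target sequences absent from this strain was not tested, and no biological explanation was tested.

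The low-GC probes had a higher median log2 difference than all tested probes in the fit of all arrays (0.274 against 0.0863), although camera did not call the class. The excess was smaller with the slide as a block (0.213 against 0.146) and with normexp and quantile normalisation (0.139 against 0.027). It was not smaller with normexp and the 75th percentile shift (0.316 against 0.121). In the fit of all arrays, residual background in dim probes alone is argued against, since the median of 0.274 lay above the central 95% (0.053 to 0.188) of 10000 lists of other probes matched on mean signal. Within slide 2 the median of 0.213 lay inside the central 95% of matched lists there (0.095 to 0.226), as a difference between the slides would give, so the slides may account for the excess, although this rests on a single 28 °C array. A trend with GC content also stays open, since probes of 45 to 50% GC exceeded those of 55 to 60% by 0.084 (bootstrap interval 0.024 to 0.118), which spans the limit of 0.053 set for the test. The temperature difference itself stays open too, untested against these.

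Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 2812 changed probes or 411 changed at least 2-fold. The highest count among the other splits was 0 in limma for both, with 18 to 207 probes at an unadjusted p below 0.05. With 10 splits no share below 0.05 can be reached. Each other split also put arrays of both temperatures in each group, so the temperature difference widened the spread within groups. Their counts are therefore not a measure of the calls to be had without a temperature difference.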
